A study of Mus musculus with 4 samples.

How the data were processed

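The series holds 4 droplet single-cell RNA libraries of mouse splenocytes, 1 per group: young wild type (WT), aged WT, aged miR-146a knockout, and aged miR-146a knockout with miR-155 deleted in T cells (called the double knockout). The WT mice carried the floxed miR-155 gene. Aged mice were 15 months old. Each aged library came from a pool of 3 to 6 mice. The age of the young mice and the size of their pool are not given in the sources used here. Live CD45+ cells with low forward and side scatter, a gate meant for lymphocytes, were sorted before 10x Genomics library preparation. The labels name both 3' and 5' chemistry, with 3' in the series design and the library line; the count matrices cannot tell which was used.

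The authors deposited raw UMI counts (unit: counts) for 31053 genes and 27577 barcodes called as cells. According to the submitters' processing notes, the matrices were made with Cell Ranger 3.0.0 on mm10, with no further normalisation. The authors also deposited a cell type name for 24143 of these barcodes (unit: other, 16 names); how the names were assigned is not given in the sources used here. Annotated cells held between 501 and 9001 UMIs. Barcodes without a name had mostly a mitochondrial share of at least 5% or more than 9000 UMIs. They were left out of the comparisons and described apart.

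Types were grouped into 3 classes: T cells (Nai Cd4, Mem Cd4, Nai Cd8, Mem Cd8, Early Act Cd8), B cells (Fo B, MZ B, Trans B, GC Centroblast, GC Centrocyte) and myeloid cells (Gran, Ly6c+ Mono, Ly6c- Mono, DC/Mac). NK and T/B dbl cells stayed outside the classes. The share of each type among annotated cells was compared as a ratio with its Katz interval. Shares have exact Clopper-Pearson intervals. UMIs were summed per class and library and given as CPM, UMIs per 1000000 UMIs of that class. Sums have exact Poisson intervals, and ratios of 2 libraries have conditional binomial intervals. Every interval is at 95%. With 1 library per group there are no replicates, so no test between groups was run. The intervals cover counting error only, not differences between mice, pools or preparations. Where a library had no UMI of a gene, the fold was computed against a floor of 3 counts and is given as "at least".

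The comparisons were aged WT with young WT, miR-146a knockout with aged WT, and double knockout with miR-146a knockout. Values of the double knockout against aged WT are given beside them. Up to 4 genes per direction, class and comparison were named. They were ranked by the bound of the ratio's interval nearest to 1, among genes with at least 50 UMIs in at least 20 cells of the library where they were higher and with an interval wholly beyond 1.5-fold. Both libraries needed at least 100 cells of the class. Genes below 20% of their level in the class with the highest level in that library were left out, as free RNA could account for them. Immunoglobulin, T cell receptor, haemoglobin, mitochondrial and ribosomal protein genes, Xist, Tsix, Y-linked genes, and names of the form Gm with a number or ending in Rik were left out too (9930111J21Rik2 does not end so and was kept). Some genes that this rule names are not used here. Mir155hg was added, and the members of each list with the highest and lowest ratio could be. Other list members given as examples, and the types in which a gene was read, were chosen after their values were seen.

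For 28 gene lists, the median log2 ratio was taken over members with at least 20 UMIs, with 1 count added to each sum. A member counted as higher or lower when its ratio was at least 1.5-fold up or down, a statement of size that takes no account of its interval. The interval of a median comes from 500 Poisson redraws. Its percentile is its place among 10000 random lists matched for level in 20 bins, which describes these libraries and is not a test between groups. In T cells the lists were T follicular helper, regulatory T, naive T, cytotoxic T, effector memory T and T cell exhaustion. In B cells they were germinal centre B, plasma cell, age-associated B, marginal zone B and follicular B. NF-kB response, type I interferon response, interferon gamma response, literature targets of miR-146a and of miR-155, cell cycle, and immediate early and heat shock genes, which tissue dissociation induces, were read in all 3 classes. MHC class II was read in B and myeloid cells, and neutrophil and monocyte and macrophage genes in myeloid cells. Check lists held erythroid, platelet, NK, B cell, T cell, sex-linked and miR-146a-neighbouring genes. Genes with an 8mer seed site for miR-146a or miR-155 in a 3' UTR of the GENCODE annotation of GRCm38 were compared, where they had at least 50 UMIs in the class over both libraries, with random genes matched for level and 3' UTR length. An annotated 3' UTR was found for 20947 of the 31053 genes, and the others were not searched. A gene was called alike in T and B cells when its ratio's interval lay wholly beyond 1.5-fold in the same direction in both classes, with at least 50 UMIs of each class in 1 of the libraries; immunoglobulin, T cell receptor, haemoglobin, mitochondrial, ribosomal protein and sex-linked genes, repeated symbols and genes without a position were left out.

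Groups, lists, comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives fixed then were a denominator of B and T lineage cells, a filter of at least 500 UMIs and under 5% mitochondrial UMIs, removal of Scrublet doublets, classes by highest marker score, TMM scaling (edgeR 4.0.16, used for scaling only), scaling without immunoglobulin, T cell receptor, ribosomal, mitochondrial and haemoglobin genes, standardising to the aged WT mix of types with at least 30 cells in both libraries, a mean over cells of counts per 10000, list minima of 5 and 100 UMIs, the mean over list members, 7mer-m8 or 8mer sites, and a minimum of 200 UMIs for seed genes. Alternatives chosen after seeing the data were B lists and GC Centrocyte shares without cells led by erythroid, platelet or progenitor markers, shares of each type over cells with the highest marker score for its class, the addition of unannotated barcodes above 9000 UMIs, myeloid lists without Gran, and T lists within each T type.

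The gene ratios and lists were tested on simulated data built from the T cell sums of the miR-146a knockout and aged WT libraries. Counts were drawn as Poisson, the model behind the intervals, so the test checks the computation and not the spread between pools. Changed genes were drawn from those with at least 100 UMIs over both libraries, so the rates do not cover genes with fewer. The interval covered the truth for 96.1% of 9815 genes with no difference. It was clear of 1 for 100% of the 34 genes raised 2-fold and for 94.1% of those lowered to 0.5 of their level. It was clear of 1 for 94.1% of those raised 1.5-fold, but for 70.6% of those lowered to 0.667 of their level. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9, and R 4.3.3, were used.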

Results

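Splenocytes of 4 groups of C57BL/6 mice were profiled by 10x Genomics single-cell RNA sequencing, with 1 library per group and no replicates. The libraries held 7626 barcodes (young WT), 6952 (aged WT), 5702 (aged miR-146a knockout) and 7297 (aged double knockout). Their total UMI counts were 19072791, 17561683, 19995131 and 22399381. The authors' cell type names covered 6821, 5896, 4832 and 6594 of these barcodes, with a median of 2274, 2054, 2649.5 and 2269 UMIs per cell. miR-146a limits NF-kB signalling and miR-155 promotes activation of T cells. The comparisons ask what differs with age in WT spleens, with loss of miR-146a in aged mice, and with the further loss of miR-155 in T cells.

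Mir155hg (ENSMUSG00000097418), the host transcript of miR-155 on chromosome 16 from 84703167 to 84715245 of mm10, was read first in each library. Its level in T cells was 3.26 CPM in young WT, 9.86 in aged WT, 17.0 in the miR-146a knockout and 12.5 in the double knockout, from 26, 45, 67 and 63 UMIs. In B cells it was 6.00, 5.69, 7.60 and 8.04 CPM. The hairpin deleted in the double knockout lies at 84714140 to 84714204, inside the host transcript and away from both of its ends. A tag at the 3' or the 5' end, both of which the labels name, need not read it, so these values do not check the deletion. No host transcript of miR-146a, whose hairpin lies on chromosome 11 from 43374397 to 43374461, was measured. Genes neighbouring miR-146a had a median log2 ratio of 0.06 with age, −0.14 in the miR-146a knockout against aged WT and −0.05 in the double knockout against the miR-146a knockout. None of them lay beyond 1.5-fold. In every pool Xist was at most 0.164 CPM and the Y-linked gene Ddx3y lay between 63.3 and 80.3 CPM. Y-linked genes had median log2 ratios of −0.28, −0.08 and −0.03 in the same 3 comparisons.

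In the aged WT spleen naive T cells made up 12.7% of annotated cells against 31.6% in the young spleen, a share 2.5-fold lower (ratio 0.400, interval 0.371 to 0.432). Memory T cells took 16.9% against 9.94%, a ratio of 1.70 (1.55 to 1.86). B cells as a whole were 63.1% against 48.6% (ratio 1.30, 1.26 to 1.34). NK cells were 1.65% against 3.34% (0.492, 0.389 to 0.623), and Ly6c- monocytes 0.933% against 0.396% (2.36, 1.49 to 3.73). Cells annotated as GC Centroblast were 7.63% against 5.15% (1.48, 1.30 to 1.70). Cells annotated as GC Centrocyte were 0.865% against 0.645%, with an interval of the ratio from 0.897 to 2.00 that includes 1. With every unannotated B or plasma barcode above 9000 UMIs counted in, the ratio was 2.03 against 1.34, but 55 of the barcodes added in aged WT and 12 of those in young WT had their highest marker score for plasma cells. These shares, and those in the knockout libraries, are of live CD45+ cells inside a gate with low forward and side scatter and of barcodes with at most 9001 UMIs.

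**Figure D1:**
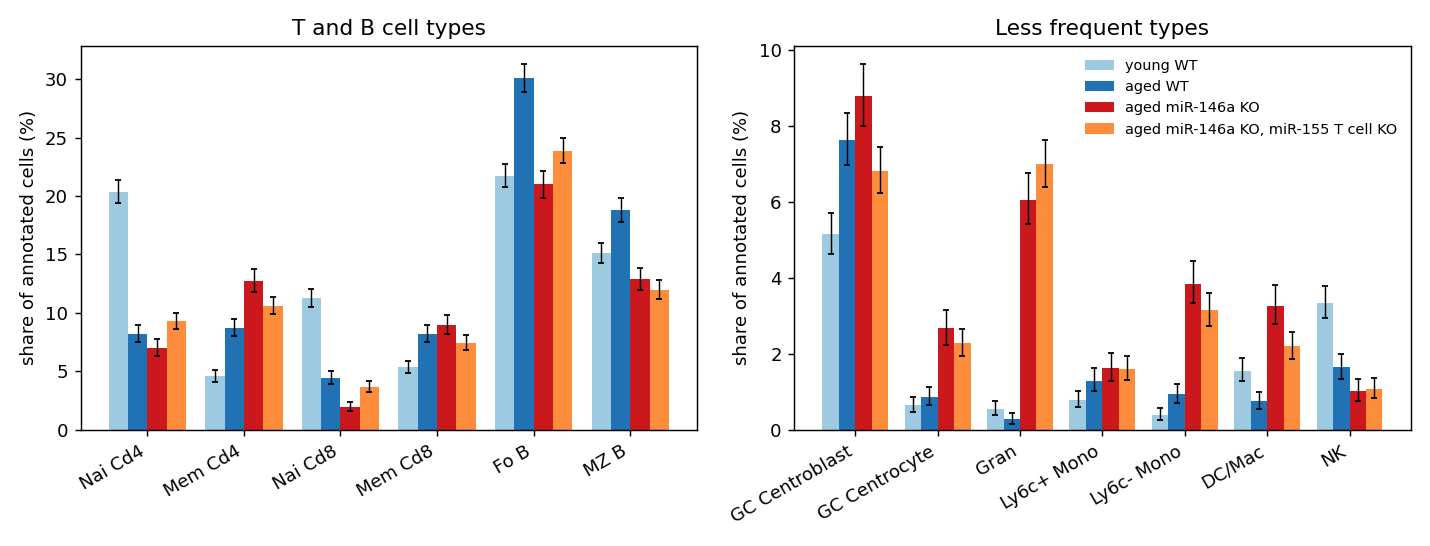
Share of annotated cells (%, linear axis) of each cell type in the 4 libraries; bars are single libraries and error bars are exact Clopper-Pearson 95% intervals, which cover counting error only. Gran cells took 6.06% and 6.99% in the 2 knockout libraries against 0.542% and 0.271% in the WT libraries.

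T cells of the aged WT library carried more transcripts of memory, helper, regulatory, cytotoxic and inhibitory receptor genes than those of the young library. Spp1 (osteopontin) was at 48.9 CPM against no UMI in young T cells, at least 130-fold higher. Of its 223 UMIs, 194 lay in Mem Cd4 cells. Sostdc1, a secreted antagonist of BMP and Wnt signalling, was at 136 against 4.88 CPM (27.9-fold, 20.2 to 39.6). Il1r2, a decoy receptor for IL-1, was at 22.6 against 0.376 CPM, a ratio of 60.1 (19.996 to 296) that rests on 3 young UMIs. Pygo1 was at 18.2 CPM against 0 (at least 48.4-fold) and was alike higher in B cells. It was also at 0 CPM in T and B cells of both aged knockout libraries, so it marked the aged WT pool and not age alone. Lower in aged T cells were Ly6c1 (19.3 against 100 CPM, 5.19-fold lower, 4.16 to 6.55), Pdlim4 (4.89-fold, 3.61 to 6.76), Mir142hg (3.89-fold, 2.66 to 5.87) and the naive cell marker Dapl1 (238 against 642 CPM, 2.69-fold, 2.52 to 2.88). With the aged WT mix of T cell types imposed on both libraries, the log2 ratio of Sostdc1 was 3.61 against 4.77, that of Il1r2 4.78 against 5.51 and that of Pdlim4 −1.57 against −2.26.

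The T cell lists pointed the same way. The T follicular helper list had a median log2 ratio of 1.47 (1.32 to 1.81), with 10 of 13 measured members higher by over 1.5-fold. Il21, the helper cytokine, was 16.1-fold higher (6.42 to 51.9), the inhibitory receptor gene Pdcd1 7.80-fold (6.07 to 10.1) and the follicle homing receptor gene Cxcr5 4.39-fold (3.27 to 5.95). Within Mem Cd4 cells the median of this list was 1.33. The T cell exhaustion list had a median of 1.87 (1.48 to 2.30) with 8 of 8 members higher, Lag3 the most (120 against 6.39 CPM, 18.8-fold, 14.1 to 25.6). In the regulatory T list, with a median of 1.46 (1.16 to 1.73), 8 of 10 members were higher. Nrp1 was 8.25-fold higher (6.55 to 10.5) and Lrrc32 had a ratio of 0.462. Foxp3, the lineage factor of regulatory T cells, was at 24.8 against 12.5 CPM. The cytotoxic T list had a median of 1.51 (1.14 to 1.67) and 12 of 15 members higher, with Gzmk 13.7-fold higher (9.82 to 19.7) and Gzma at a ratio of 0.353. Among 14 effector memory genes (median 1.36, 1.28 to 1.53) 12 were higher, with S100a6 at 646 against 82.5 CPM. The naive T list had a median of −0.36 (−0.44 to −0.27) with 5 of 12 members lower, among them Lef1 (ratio 0.482). NF-kB response genes had a median of 0.68 (0.59 to 0.91) with 8 of 16 higher, and interferon gamma response genes 0.33 with 3 of 14 higher, Iigp1 among them.

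These medians differed between types. With the aged WT mix in both libraries the cytotoxic T median was 0.64 and the T follicular helper median 0.98. Within Nai Cd4 and Nai Cd8 cells the naive T median was −0.09 and −0.01. In Nai Cd8 cells the T follicular helper median was −0.11, and in Mem Cd8 cells the regulatory T median was −0.29. The median of all genes in T cells was 0.11 with age, a shift that TMM scaling moved by −0.13. Type I interferon and cell cycle genes in T cells had medians of −0.03 and 0.30.

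B cells of the aged WT library showed higher age-associated B genes and lower type I interferon response genes. The age-associated B list had a median log2 ratio of 1.09 (0.65 to 1.20) with 7 of 10 members higher, from Cd80 (ratio 2.67, 1.16 to 6.88) to Zeb2 (1.17). Tbx21, which encodes the T-bet factor of these cells, had a ratio of 2.36. Dnm3 was at 6.39 against 0.782 CPM (8.17-fold, 3.52 to 23.2), mostly in cells annotated as GC Centroblast (27.6 against 3.06 CPM). Fos (4.32-fold, 3.46 to 5.45) and Fosb (4.90-fold, 3.16 to 7.92), immediate early genes that tissue dissociation also induces, were higher, beside a median of 0.24 for the immediate early and heat shock list. Pygo1 was at 17.8 CPM against 0 (at least 45.4-fold), and at 0 CPM in B cells of both aged knockout libraries. Ifi208, an interferon-inducible gene, was at 1.98 against 24.3 CPM (12.3-fold lower, 7.46 to 21.5). It was lower in T cells too (25.2 against 65.2 CPM, ratio 0.386, 0.313 to 0.474), so it is not particular to B cells. Cd36 was 2.41-fold lower (1.90 to 3.08) and Mir142hg 2.28-fold lower (1.89 to 2.76). Gzma was 4.67-fold lower in B cells (3.24 to 6.88), beside a level in NK cells of 6323 against 12778 CPM, and B cells should lack it. Median depths of the B class were 1928 and 1940.5 UMIs. The type I interferon list had a median of −0.49 (−0.65 to −0.28) with 8 of 17 members lower, Rsad2 (ratio 0.334) the most.

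Other B cell lists differed less with age. The germinal centre B median was 0.42 (0.20 to 1.02) with 5 of 11 members higher, among them S1pr2 (3.45) and Mef2b (3.14). The plasma cell median was 0.02, although Jchain, the joining chain of secreted antibody, was at 75.2 against 27.6 CPM in B cells; in T cells, which should lack it, it was at 62.0 against 18.7 CPM. Median T cell depths were 2279 and 2613 UMIs. Marginal zone B (−0.13), follicular B (0.04), NF-kB (0.11), interferon gamma (0.23), MHC class II (0.15) and cell cycle (−0.21) medians lay within 0.25 of 0. Literature targets of miR-146a had medians of 0.43 in T cells and 0.12 in B cells, and targets of miR-155 of 0.09 and −0.02.

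In myeloid cells of the aged WT library, Siglech (21.2 against 206 CPM, 9.71-fold lower, 5.73 to 17.7) and Ccr9 (11.6-fold lower, 5.13 to 32.6), both expressed by plasmacytoid dendritic cells, were lower, as were Cd209d (6.74-fold, 3.69 to 13.5) and P2ry14 (6.50-fold, 3.10 to 15.7). The DC/Mac share was 0.746% against 1.55% (ratio 0.480, 0.338 to 0.681). MHC class II genes had a median log2 ratio of −0.71 (−0.77 to −0.54) with 6 of 10 lower, from H2-Oa (ratio 0.447) to H2-DMb1 (0.843). Within types the direction differed: the median was 0.10 (−0.01 to 0.25) in Ly6c+ monocytes, 0.51 (0.25 to 0.94) in Ly6c- monocytes and −0.14 (−0.23 to −0.07) in DC/Mac cells. Type I interferon genes had a median of −0.55 (−0.74 to −0.27) with 8 of 17 lower, Bst2 (0.414) the most, and −0.89 within Ly6c+ monocytes. Tppp3 was 3.96-fold higher (3.03 to 5.23), Fos 3.84-fold (2.58 to 5.86) and Serpinb1a 3.06-fold (2.08 to 4.57). Neutrophil genes had a median of 2.00 (1.58 to 2.11) with 8 of 12 higher, from Ngp (18.0) to Cxcr2 (0.264), among 16 aged and 37 young cells annotated as Gran. Chil3 was 2.70-fold higher (2.34 to 3.13), but with the aged WT mix of types (Ly6c+ Mono and DC/Mac cells only) its log2 ratio was −0.04 against 1.43. On the same mix those of Fos and Serpinb1a were 1.33 and 0.99, and those of Siglech, Ccr9, Cd209d and P2ry14 were −2.34, −2.56, −1.98 and −1.86, against −3.20, −3.34, −2.65 and −2.55. The list of immediate early and heat shock genes, which mark dissociation of the tissue, had medians of 0.39 in T cells, 0.24 in B cells and 0.69 in myeloid cells, with Hspa1a at the highest ratio in each (6.56, 5.52 and 7.43). The remaining myeloid medians were 0.15 for NF-kB, −0.20 for interferon gamma, −0.00 for monocyte and macrophage (−0.89 as a mean over members and −0.84, −1.38 to −0.44, within DC/Mac cells), 0.39 for cell cycle, −0.11 for miR-146a target and 0.06 for miR-155 target genes.

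In the miR-146a knockout library, myeloid cells were 14.8% of annotated cells against 3.24% in aged WT (ratio 4.57, 3.91 to 5.33). Gran cells were 6.06% against 0.271%, a ratio of 22.3 (13.5 to 36.9) from 293 and 16 cells. Ly6c- monocytes (ratio 4.13, 3.06 to 5.56) and DC/Mac cells (4.38, 3.14 to 6.11) took larger shares, while Ly6c+ monocytes had a ratio of 1.25 (0.915 to 1.71). Only 19 of the 44 aged WT and 106 of the 158 knockout cells annotated as DC/Mac had their highest marker score for myeloid or dendritic cells, and over these the ratio was 6.81. Cells annotated as GC Centrocyte were 2.67% against 0.865% (3.09, 2.24 to 4.26). Naive T cells were 8.90% against 12.7% (0.703, 0.629 to 0.787), and within them Nai Cd8 cells had a share 2.30-fold lower (ratio 0.435, 0.344 to 0.549). Mem Cd4 cells were 12.7% against 8.68% (1.47, 1.31 to 1.64). NK cells had a ratio of 0.616 (0.438 to 0.867).

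T cells of the miR-146a knockout library had higher levels of cytotoxic effector genes, Ccl3 and Ccl4, and lower levels of naive genes, than those of aged WT. Gzmb, the granule protease granzyme B, was at 163 against 14.0 CPM (11.6-fold, 9.0 to 15.3). Of its 645 UMIs, 617 lay in Mem Cd8 cells, where it was at 458 against 38.0 CPM. The chemokine genes Ccl3 (107 against 6.36 CPM, 16.8-fold, 11.5 to 25.4) and Ccl4 (223 against 40.5 CPM, 5.49-fold, 4.68 to 6.47) were higher too. Cells annotated as Early Act Cd8, a set of 35 cells, held 139 of the 421 Ccl3 UMIs and 331 of those of Ccl4, and the 43 such cells of the double knockout held 0 and 2. Lower were Igfbp4 (47.4 against 251 CPM, 5.30-fold, 4.54 to 6.22), the gut homing receptor gene Ccr9 (7.46-fold, 4.44 to 13.4) and Auts2 (9.15-fold, 4.22 to 23.5). Averaged over cells, the log2 ratio of Ccl3 was 3.40 against 4.02 and that of Gzmb 2.93 against 3.52; with the aged WT mix of types those of Ccl3, Igfbp4 and Auts2 were 3.35, −1.52 and −2.10.

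The naive T list had a median log2 ratio of −1.23 (−1.30 to −1.10) with 8 of 12 members lower. Lef1 (ratio 0.404), Ccr7 (0.403) and Satb1 (0.385) lay between Igfbp4 (0.189) and Il7r (0.895). Its median was −0.92 within Nai Cd4 cells and −0.49 within Nai Cd8 cells. Every one of 11 measured regulatory T genes was higher (median 1.02, 0.94 to 1.29), from Il10 (3.47, 1.32 to 10.7) to Nrp1 (1.55). Foxp3 was at 62.6 against 24.8 CPM (2.53-fold, 2.01 to 3.19). The cytotoxic T median was 0.80 (0.60 to 1.10) with 11 of 15 higher and Klrd1 (0.693) at the low end. Of 10 T cell exhaustion genes 8 were higher (median 1.05, 0.83 to 1.31), with Havcr2 at 10.1 against 0.657 CPM, a ratio of 15.4 (4.91 to 77.9) that rests on 3 UMIs in aged WT. NF-kB response genes had a median of 0.65 (0.58 to 0.80) with 9 of 16 higher, among them Cd83 (2.40) and the inhibitor gene Nfkbia (1.67). The effector memory median was 0.33 (0.26 to 0.41), from S100a4 (2.85) to Ly6c2 (0.805). The T follicular helper median was 0.54 (0.40 to 0.76) with 6 of 13 higher, led by Pdcd1 (213 against 75.2 CPM, 2.84-fold, 2.5 to 3.23), but within Mem Cd4 cells it was −0.10. The T cell cycle median was 0.47 (0.38 to 0.82) with 5 of 11 higher, and −0.03 within Mem Cd4 cells. Interferon gamma and type I interferon medians were 0.36 and 0.20.

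Literature targets of miR-146a had a median log2 ratio of 0.50 (0.28 to 0.62) in T cells, percentile 100 among the random lists, with 4 of 12 higher. Within Nai Cd8 cells the median was −0.18. The double knockout, which also lacks miR-146a, showed no such rise against aged WT in T cells. In the miR-146a knockout the known signalling targets Irak2 (1.62, 1.10 to 2.41) and Irak1 (1.29, 1.02 to 1.63) lay above 1. Traf6 had a ratio of 1.47 with an interval of 0.955 to 2.29 that includes 1, and Cxcr4 (0.726) was lowest. The median was 0.05 in B cells, and −0.35 in myeloid cells against −0.41 for random lists (percentile 63.2). The 383 genes with an 8mer seed site for miR-146a and at least 50 UMIs in T cells of both libraries together had a median of 0.05 in T cells, the same as matched random genes (percentile 39.7). In B cells it was −0.07 against −0.06 (410 genes), and in myeloid cells −0.36 against −0.37 (257 genes), so no shift of seed genes was detectable at this depth. Literature targets of miR-155 had medians of 0.10, −0.10 and −0.46 in T, B and myeloid cells, near those of random lists (percentiles 70.4, 17.5 and 31.5).

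**Figure D2:**
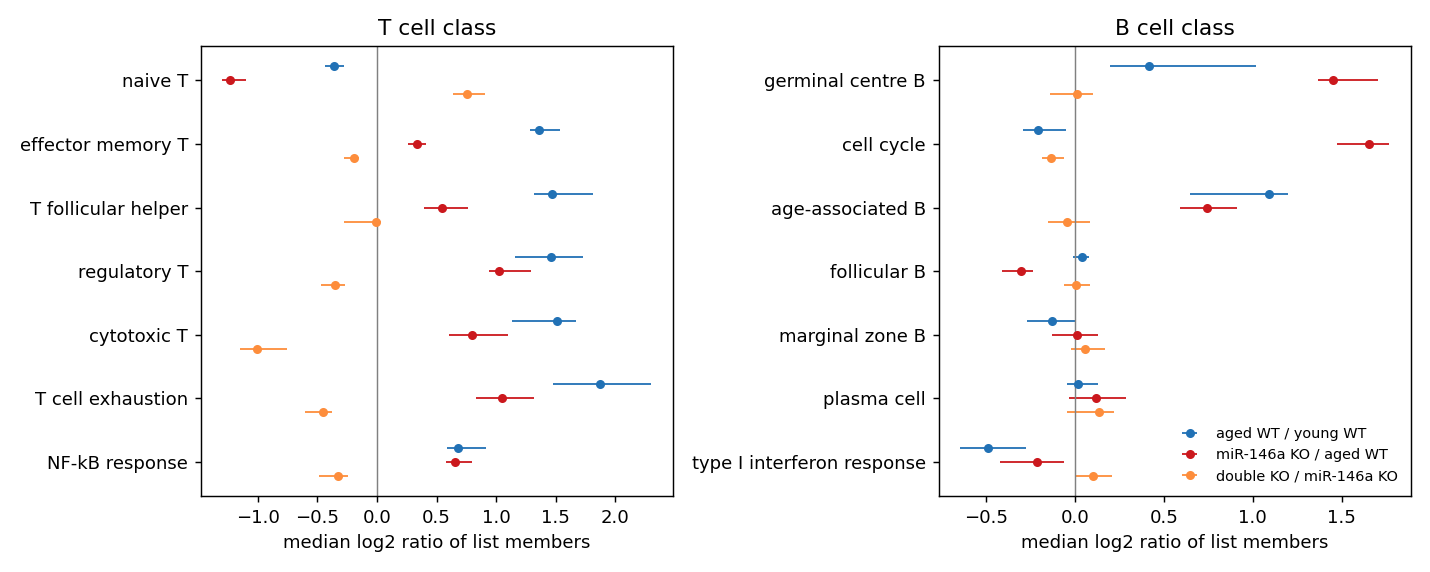
Median log2 ratio (linear axis) of the members of gene lists in T cells and in B cells for the 3 comparisons; points are medians over measured members of 1 library against another and lines are 95% intervals from Poisson redraws, which cover counting error only. Naive T genes lie at −1.23 in the miR-146a knockout against aged WT and at 0.76 in the double knockout against the miR-146a knockout.

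B cells of the miR-146a knockout library showed more germinal centre and cell cycle transcripts. The germinal centre B list had a median log2 ratio of 1.45 (1.37 to 1.71) with 11 of 12 members higher, among them Mybl1 (9.66, 4.42 to 25.0), Gcsam (5.82, 3.59 to 9.92) and Mef2b (40.5 against 14.8 CPM). Bcl6, the master factor of germinal centre B cells, had a ratio of 0.924. With the aged WT mix of B cell types the list's median was 0.68. Cell cycle genes had a median of 1.65 (1.47 to 1.77) with 13 of 16 higher, from Ube2c (5.28) to Pcna (1.10). Age-associated B genes had a median of 0.74 (0.59 to 0.91) with 8 of 12 higher, Itgam the most (6.38, 2.18 to 25.4). Itgam and Fcer1g of this list are also among the myeloid markers used here. The myeloid gene Lyz2 was found in 24.5% of B cells against 6.70% in aged WT, so free myeloid RNA was not told apart from expression of these genes. Vpreb1, which encodes part of the surrogate light chain, was at 53.4 against 0.349 CPM (153-fold, 52.0 to 745, from 3 UMIs in aged WT). Dntt, the terminal transferase (15.2 against 0 CPM, at least 43.6-fold), and the recombinase gene Rag1 (7.35 against 0 CPM, at least 21.1-fold) were higher too. They lay mostly in Trans B cells, which held 343 Vpreb1 UMIs in the miR-146a knockout and 222 in the double knockout. Follicular B genes had a median of −0.30 (−0.41 to −0.23), lowest Ccr7 (0.537). Tsc22d3, a glucocorticoid-induced gene, was 2.27-fold lower (2.10 to 2.45). It was lower in T cells (ratio 0.531, 0.464 to 0.608) and myeloid cells (0.377, 0.308 to 0.462) too, so it is not particular to B cells. The interferon-inducible GTPase genes Irgm1 (3.66-fold lower, 2.94 to 4.60) and 9930111J21Rik2 (3.46-fold, 3.05 to 3.93) were also lower, and both lie within 20 Mb of the deleted miR-146a gene.

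The cells annotated as GC Centrocyte carried the germinal centre and cycling genes. Over the 4 libraries Mki67 was at 308 CPM in them and 1.85 in cells annotated as GC Centroblast. Cells annotated as GC Centroblast were led by Dnm3, Bhlhe41 and Fcrl5. The other B lists in this comparison lay closer to 0: plasma cell 0.12, marginal zone B 0.01, NF-kB 0.08, interferon gamma 0.08, type I interferon −0.22, MHC class II −0.12 and immediate early −0.41. Haemoglobin gene Hbb-bs was at 351 against 1.63 CPM in B cells, but 2255 of its 2725 UMIs lay in 6 cells annotated as GC Centrocyte and led by erythroid, platelet or progenitor markers. The erythroid list median was 6.69 in B cells (3.58 without cells so led), 2.73 in T cells and 4.62 in myeloid cells, beside these B cell differences.

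**Figure D3:**
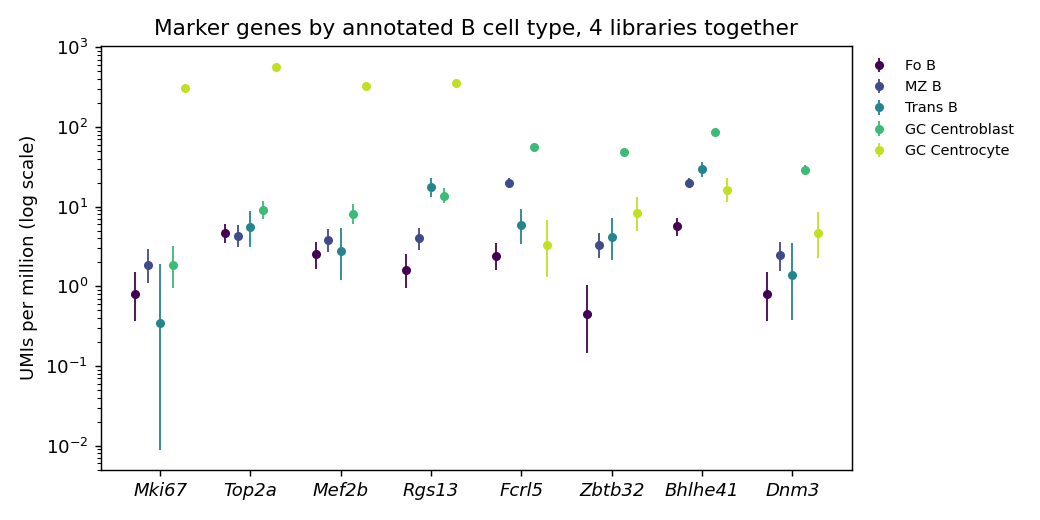
Level of marker genes (UMIs scaled to 1000000 per type, log axis) in the 5 annotated B cell types with the 4 libraries together; points are sums over cells and lines are exact Poisson 95% intervals, which cover counting error only. Mki67 is at 308 in GC Centrocyte and 1.85 in GC Centroblast.

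In myeloid cells, the miR-146a knockout library differed from aged WT in which cells the class held, and Gran made up 293 of its cells. Neutrophil genes had a median log2 ratio of 3.43 (3.26 to 3.45) with 11 of 12 higher, among them S100a8 (94435 against 8793 CPM), Camp (10.8-fold) and Ly6g (15.2, 10.2 to 23.5), with Csf3r at 0.955. The neutrophil median was 0.44 (0.36 to 0.50) within Gran but 3.60 (3.08 to 5.38) without them, 4.30 in Ly6c+ monocytes, 3.63 in Ly6c- monocytes and 5.93 in DC/Mac cells, so the Gran in the class do not account for it alone; free RNA was not told apart from expression in these types. The complement genes C1qa (302 against 1.41 CPM), C1qb (403 against 5.65 CPM) and C1qc (229.97 against 1.41 CPM) were higher, with ratios of 214 (38.3 to 8466), 71.4 (27.8 to 262) and 163 (29.1 to 6439); C1qa and C1qc rest on 1 UMI each in aged WT. The aged WT library was itself low for these genes: C1qa was at 156 CPM in young WT, whose DC/Mac cells held 109 C1qa UMIs against 0 in aged WT and 855 in the miR-146a knockout. Saa3, an acute phase protein, was at 275 CPM against 0 (at least 64.8-fold), with 777 UMIs in Ly6c+ monocytes. Lower were Stxbp6 (12.005-fold, 7.03 to 21.4), Hpgd (6.77-fold, 4.93 to 9.35), the dendritic cell lectin gene Cd209a (6.27-fold, 4.67 to 8.44) and Trf (5.75-fold, 4.35 to 7.62). Averaged over cells, the log2 ratio of C1qa was 5.49 against 6.74, that of C1qb 4.69 against 5.84, that of C1qc 5.11 against 6.35 and that of Hpgd −1.91 against −2.75. That of Stxbp6 was −4.16 averaged over cells and −2.14 with the aged WT mix of types without Gran, against −3.54, and that of Saa3 6.79 and 9.05 against 7.61.

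All genes of the myeloid class had a median log2 ratio of −0.38, which TMM scaling moved by 0.38, so the other myeloid lists are read against it. Below it lay MHC class II (−1.07, −1.2 to −1.0, 10 of 10 lower, from H2-DMa at 0.387 to H2-Ob at 0.614), type I interferon (−0.89, 13 of 17 lower, Ifit3 0.161), immediate early genes (−0.85) and NF-kB response genes (−0.76, 9 of 17 lower). Without Gran the MHC class II median was −0.46, the type I interferon median −0.46 and the NF-kB median −0.05. By type, the MHC class II median was −0.77 in Ly6c+ monocytes, −1.23 in Ly6c- monocytes and −0.64 in DC/Mac cells, but 0.52 (−0.31 to 0.91) in Gran. The B cell marker Cd79a was at 87.1 CPM in the myeloid class against 185 in aged WT. Of the DC/Mac cells, 14 of 158 had their highest marker score for B cells, against 20 of 44 in aged WT. Of the Ly6c- monocytes, 5 of 186 did, against 6 of 55. B cell RNA was therefore not told apart from MHC class II expression in these types. The type I interferon median was −0.69 in Ly6c+ monocytes and 0.26 (−0.11 to 0.50) in DC/Mac cells, and the NF-kB median 0.13 and −0.40 in these types. Cell cycle genes had a median of 1.44 (1.14 to 1.98) with 12 of 15 higher, which differed by type: 3.97 (3.44 to 4.69) in Ly6c+ monocytes, 0.99 (0.71 to 1.71) in DC/Mac cells and −0.01 (−0.54 to 0.38) in Ly6c- monocytes. In Gran it was −0.98 against only 16 aged WT cells, at percentile 13.5 among random lists, and is not read as a fall. Monocyte and macrophage genes had a median of −0.48, but 0.97 as a mean over members, 0.11 (−0.03 to 0.36) without Gran and 2.13 within DC/Mac cells, so no direction is given for the class. Interferon gamma response genes had a median of −0.44, with Irgm1 lowest (0.218).

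Some differences of the miR-146a knockout library from aged WT were alike in T and B cells, that is, with an interval of the ratio wholly beyond 1.5-fold in the same direction in both classes. Of 29 such genes, 19 were higher and 10 lower. Pygo1 (chromosome 9, 72925645 to 72952181) was at 0 CPM in both, at least 23.9-fold lower in T cells and 46.0-fold lower in B cells than in aged WT. In young WT it was at 0 CPM in both classes too. Tpm3-rs7 was at 285 against 9.42 CPM in T cells (30.2-fold, 22.3 to 42.0) and 253 against 7.09 in B cells (35.6-fold, 27.6 to 46.8). Its near-identical copy Tpm3, a tropomyosin gene, was at 256 against 494 CPM in T cells, and the summed level of both was 541 against 503 CPM. S100a8 was at 337 CPM in B cells and 386 in T cells of the miR-146a knockout against 9.18 and 7.23 in aged WT. It was found in 62.3% and 62.6% of B and T cells, which should lack it, against 1.99% and 1.88%. B cells had medians of 2729 and 1928 UMIs in these libraries, T cells 2265 and 2279.

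**Figure D4:**
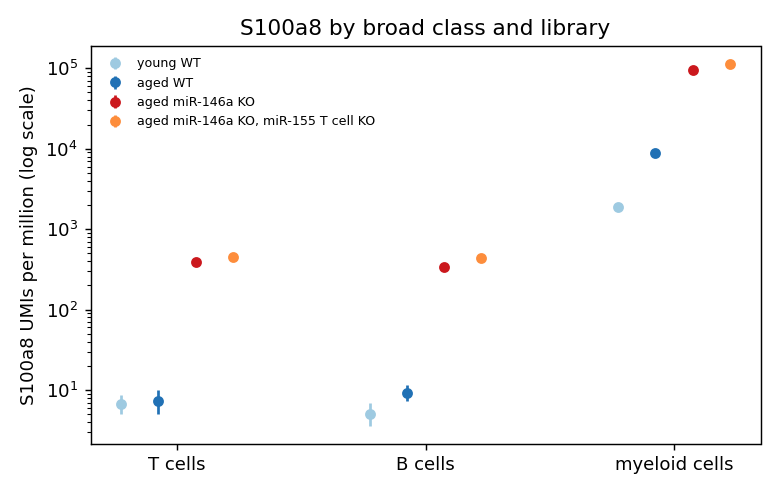
Level of S100a8 (UMIs scaled to 1000000 per class, log axis) in T, B and myeloid cells of the 4 libraries; points are class sums of single libraries and lines are exact Poisson 95% intervals, which cover counting error only. B cells lie at 337 and 440 in the 2 knockout libraries against 5.09 and 9.18 in the WT libraries.

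In the double knockout library, naive T cells were 12.9% of annotated cells against 8.90% in the miR-146a knockout (ratio 1.45, 1.30 to 1.62), close to the 12.7% of aged WT. Memory T cells were 18.0% against 21.7% (0.831, 0.771 to 0.895). Nai Cd8 cells had a ratio of 1.89 (1.49 to 2.40) and Mem Cd4 cells of 0.833 (0.752 to 0.922). Cells annotated as GC Centroblast had a ratio of 0.776 (0.683 to 0.881) and as GC Centrocyte of 0.852 (0.675 to 1.08). Gran cells were 6.99% against 6.06% (1.15, 1.00 to 1.33), and DC/Mac cells had a ratio of 0.672 (0.538 to 0.840).

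T cells of the double knockout library had lower levels of cytotoxic genes, Ccl3 and Ccl4, and higher levels of naive genes, than those of the miR-146a knockout. Gzmb was at 22.4 against 163 CPM (7.30-fold lower, 5.97 to 8.99), Ccl3 at 22.6 against 107 (4.72-fold, 3.83 to 5.86), Ccl4 at 75.7 against 223 (2.94-fold, 2.61 to 3.33) and Gzma at 9.91 against 35.2 (3.55-fold, 2.56 to 5.01). In Mem Cd8 cells Gzmb was at 69.4 against 458 CPM, while in NK cells it was at 546 against 325 CPM. Higher were Dapl1 (232 against 59.0 CPM, 3.93-fold, 3.42 to 4.55), Ly6c1 (8.25-fold, 4.44 to 17.0), Ccr9 (4.06-fold, 2.36 to 7.43) and Auts2 (5.81-fold, 2.63 to 15.2). Averaged over cells, the log2 ratio of Ccl3 was −1.61 against −2.23. With the aged WT mix of types those of Ccl4, Dapl1 and Auts2 were −0.94, 1.28 and 1.77.

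The naive T list had a median log2 ratio of 0.76 (0.64 to 0.90) with 8 of 12 members higher, among them Ccr7 (2.25, 2.00 to 2.55) and Lef1 (2.04), and Il7r (1.12) at the low end. Of 15 cytotoxic T genes 9 were lower (median −1.0, −1.15 to −0.76), with Klrd1 (1.40) at the high end. Its median was −0.80 within Mem Cd8 cells and −0.11 within Mem Cd4 cells. T cell exhaustion genes had a median of −0.45 (−0.61 to −0.38) with 4 of 10 lower, among them Havcr2 (0.156) and Lag3 (0.648); within Mem Cd4 cells it was 0.17. NF-kB response genes had a median of −0.33 (−0.49 to −0.24) with 5 of 17 lower, and interferon gamma genes of −0.25. The regulatory T median was −0.35 (−0.47 to −0.27), with Foxp3 at a ratio of 0.725 (0.603 to 0.872) and 1 of 11 members lower by over 1.5-fold. Effector memory genes had a median of −0.19, but 0.20 within Mem Cd4 cells. The T follicular helper median was −0.01 (−0.28 to 0.03), from Ascl2 (1.83, 1.24 to 2.73) to Maf (0.698). T cell cycle, immediate early and type I interferon medians were −0.35, −0.20 and −0.05. Literature targets of miR-155 had a median of −0.06 in T cells, percentile 29.1, from S1pr1 (1.56) to Spi1 (0.424). The 290 genes with an 8mer seed site for miR-155 and the same minimum of UMIs had a median of −0.03 in T cells against −0.04 for matched random genes (percentile 77.2), and 0.01 against 0.03 in B cells, where miR-155 was not deleted. No shift of these genes was detectable at this depth. Literature targets of miR-146a had a median of −0.41 (−0.52 to −0.25) in T cells.

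B cells differed less between these libraries. The germinal centre B median was 0.01 (−0.14 to 0.10), from Rgs13 (1.18) to Mybl1 (0.586), and the cell cycle median was −0.13 with Ube2c (0.648) lowest. Lower were Bloc1s1 (2.11-fold, 1.72 to 2.61), Rnaset2a (1.96-fold, 1.71 to 2.23) and Nme2 (2.21-fold, 1.64 to 3.00). Bloc1s1, Rnaset2a and Nme2 were alike lower in T cells, with ratios of 0.510, 0.510 and 0.370, and in myeloid cells, with ratios of 0.561, 0.482 and 0.351, so they are not particular to B cells. Whether reads were shared with near-identical copies or overlapping genes was not tested. The remaining B medians were −0.05 for age-associated B and for miR-155 target genes, 0.14 for plasma cell, 0.06 for marginal zone B, 0.00 for follicular B, 0.10 for type I interferon, 0.05 for MHC class II, −0.08 for NF-kB, −0.09 for interferon gamma, −0.07 for miR-146a target and −0.05 for immediate early genes.

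Myeloid cells of the double knockout library, of which 461 were Gran, had lower levels of the complement genes C1qa and C1qb than those of the miR-146a knockout. C1qa was at 68.3 against 302 CPM (4.43-fold lower, 3.85 to 5.11) and C1qb at 105 against 403 (3.83-fold, 3.41 to 4.30). Saa3 (3.92-fold, 3.40 to 4.52) and Klrb1b (8.53-fold, 4.2 to 19.6) were lower too. Higher were Asprv1 (3.40-fold, 1.89 to 6.59) and the replication genes Rrm2 (2.24-fold, 1.64 to 3.09), Mcm7 (2.36-fold, 1.51 to 3.8) and Spc24 of the kinetochore (2.19-fold, 1.51 to 3.24). Cell cycle genes had a median log2 ratio of 0.47 (0.29 to 0.62) with 5 of 16 higher, and −0.03 without Gran over the same members. Against a median of all genes of −0.10, neutrophil genes lay at 0.25, MHC class II at 0.14, type I interferon at 0.09, monocyte and macrophage genes at −0.42, NF-kB at −0.31, interferon gamma at −0.23, immediate early genes at −0.29 and targets of miR-146a and miR-155 at −0.28 and −0.26. Without Gran the type I interferon median was 0.49 (0.17 to 0.57), the MHC class II median 0.37 (0.31 to 0.42) and the NF-kB median −0.09 (−0.20 to 0.04). The MHC class II median was 1.25 (1.09 to 1.49) within Ly6c- monocytes, 0.43 within DC/Mac cells, 0.22 within Gran and 0.19 within Ly6c+ monocytes. The NF-kB median was −0.33 (−0.57 to 0.10) within Gran, −0.32 (−0.51 to 0.01) within Ly6c+ monocytes and −0.25 (−0.52 to 0.02) within Ly6c- monocytes. Within DC/Mac cells it was 0.20 (−0.00 to 0.32). B cell markers scored highest in 15 of the 207 Ly6c- monocytes of the double knockout and in 5 of the 186 of the miR-146a knockout. Cd79a in the myeloid class was at 122 against 87.1 CPM. B cell RNA was not told apart from MHC class II expression here either.

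Set directly against aged WT, the double knockout library had a ratio of 1.02 (0.931 to 1.12) for the share of all naive T cells. For all memory T cells the ratio was 1.07 (0.990 to 1.15). Single types differed more: Nai Cd4 cells had a ratio of 1.13 (1.005 to 1.26) and Nai Cd8 cells of 0.822 (0.692 to 0.976). Mem Cd4 cells had a ratio of 1.22 (1.10 to 1.36) and Mem Cd8 cells of 0.905 (0.802 to 1.02). In T cells of the double knockout, list medians against aged WT were −0.13 for naive T and 0.03 for cytotoxic T genes. They were 0.39 for NF-kB and −0.01 for miR-146a target genes. The T follicular helper (0.51), regulatory T (0.84) and exhaustion (0.61) medians stayed above 0. Against aged WT, the Gran share had a ratio of 25.8, where the miR-146a knockout had 22.3, and the GC Centrocyte share 2.63, where it had 3.09. The germinal centre B median was 1.62 and the B cell cycle median 1.48, where the miR-146a knockout had 1.45 and 1.65.

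Check lists read transcripts of other cells inside each class. In T cells the NK list had a median log2 ratio of 0.36 with age, −1.62 in the miR-146a knockout against aged WT, with Klra7 (0.240) lowest, and 1.21 in the double knockout against the miR-146a knockout. B cell genes in T cells had medians of 0.56, −0.56 and −0.49, and T cell genes in B cells of −0.32, −0.47 and −0.18, in the same order. The erythroid list had a median of −1.14 in B cells and 0.35 in T cells with age. In the double knockout against the miR-146a knockout its median was −0.16 in B cells and −1.54 in T cells. The B cell value was −2.08 without cells led by erythroid, platelet or progenitor markers. It was 0.40 with the aged WT mix of types and 0.42 as a mean over cells, so its direction is not settled. Fewer than 3 platelet genes were measured in any class, so that list has no median. Pf4 in B cells was at 31.0 CPM in young WT and 0 in aged WT. Over the 4 libraries it was concentrated in cells annotated as GC Centrocyte, at 112 CPM against 0.486 in all other annotated cells. Of the young WT cells so annotated, 1 had its highest marker score for platelets.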

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

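The tests of technical explanations given here were chosen only after the results were seen. Barcodes without a cell type name and with more than 9000 UMIs were not used in the comparisons, and they stand out as a signal above that of the library taken as the control. Among them, barcodes whose highest marker score was that of plasma cells made up 0.791% of all barcodes in aged WT (55), 0.982% in the miR-146a knockout (56) and 1.10% in the double knockout (80), against 0.157% in young WT (12). Those whose highest score was myeloid made up 1.58% in the miR-146a knockout (90) and 0.891% in the double knockout (65), against 0.0863% in aged WT (6).

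Cells annotated as Gran took a share 22.3 times as large in the miR-146a knockout library as in aged WT. If as many granulocytes had been present in the aged WT suspension and were missed for their low RNA content, free S100a8 in B cells, per S100a8 UMI of a granulocyte, should be alike, but it was 15.4 times as high in the knockout library (12.3 to 19.5). That does not settle it, because a missed cell would have needed only about 155.02 UMIs, below the 525 of the shallowest annotated cell, and the aged WT content per granulocyte rests on 16 cells. A looser scatter gate in the knockout sort cannot be told apart from the genotype either, since Ly6c+ monocytes had a share ratio of 1.25 (0.915 to 1.71) but DC/Mac cells of 4.38. The loss of miR-146a stays open as the biological explanation and was not tested, with 1 pool per group.

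Cells annotated as GC Centrocyte took a share 3.09 times as large in the miR-146a knockout library as in aged WT. Counting only cells with more B than erythroid, platelet and progenitor marker UMIs left the ratio at 3.06 (2.20 to 4.26), which argues against such cells as the cause. Of the 51 aged WT cells 16, and of the 129 knockout cells 9, had their highest marker score for T cells, and over cells with the highest score for B or plasma cells the ratio was 4.04 (2.78 to 5.89), which argues against T cells counted under this name. Counting in every unannotated B or plasma barcode above the upper UMI limit left it at 2.49 (2.03 to 3.06). The greater depth of the knockout library is argued against by the germinal centre B genes themselves. Their median log2 ratio was 1.45 over the B class sums, where each cell needs a B cell name but none needs the name GC Centrocyte. With the aged WT mix of types the median was 0.68. The difference may therefore be biological, as a hypothesis only, since it was found and tested on the same 2 libraries and differences between pools or preparations remain open.

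The 29 genes that differed alike in T and B cells between the miR-146a knockout and aged WT libraries fall into sets with different candidate explanations. Of the 19 higher ones, 11 (among them S100a8, Ngp, Camp and Lyz2) had a myeloid level at least 5 times that of both other classes, consistent with free RNA of myeloid cells. For Tpm3 and Tpm3-rs7 the summed T cell level differed by a ratio of 1.07 (1.01 to 1.14), consistent with reads counted for one near-identical copy or the other. A strain segment kept around the deleted miR-146a gene is argued against for the whole set, as 26 of the genes did not lie within 20 Mb of it. Within 20 Mb lay 3 genes (Irgm1, 9930111J21Rik2 and Ccdc69). From the 1.96% of all considered genes in that window, 0.570 were expected. For those 3, at 2 separate loci, the segment cannot be told apart from an effect of the deletion. Of the 18 genes not led by myeloid cells, 3 (Wdfy1, Pygo1 and Ccpg1) lay within 1.5-fold of young WT in the knockout library. These 3 were also alike higher in aged WT than in young WT, and the double knockout differed from aged WT as the miR-146a knockout did. In T cells Ccpg1 was at 56.5 CPM in aged WT against 23.8 in young WT, 29.6 in the miR-146a knockout and 29.9 in the double knockout. Aged WT therefore stood apart for these 3, but with 1 pool per group its pool and its genotype at that age cannot be told apart. For the other genes young WT cannot decide this, because the young pool also differs in age and mix of types. Naive cells were 74.2% of its T cells against 28.4% in the knockout library. For the other genes the aged WT pool and the genotype both stay open, and the genotype was not tested.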

How the results depend on the processing

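The alternatives within single T cell types, those without Gran or without cells led by erythroid, platelet or progenitor markers, those limited to cells with the highest marker score for their class, and those that add unannotated barcodes were chosen only after the results were seen; the others named here were fixed before. Most recomputed values stayed within the interval of the main value: of 195 share ratios 184 kept within their intervals, 10 moved and 1 reversed. Of 340 gene ratios 308 kept, 31 moved and 1 reversed, and of 1275 list medians 971 kept, 285 moved and 19 reversed. All 10 seed gene medians kept. A list median that changed sign counted as reversed only where the main median lay outside the central 95% of random lists. A share ratio did so only where the interval of the main ratio excluded 1. Other changes of sign are counted as moved or kept. Among them is that of the monocyte and macrophage median in the miR-146a knockout against aged WT. The share ratio of Gran in the miR-146a knockout against aged WT ranged from 21.7 to 25.1, of myeloid cells from 4.57 to 5.21 and of GC Centrocyte from 2.49 to 4.04. That of DC/Mac cells was 6.81 over cells with the highest marker score for their class, against 4.38. The naive T share ratio ranged from 0.393 to 0.400 with age and from 1.45 to 1.47 in the double knockout against the miR-146a knockout. The memory T ratio ranged from 1.67 to 1.72 and from 0.831 to 0.846, and the age-associated B median with age from 0.83 to 1.10. TMM scaling moved the median of all myeloid genes in the miR-146a knockout against aged WT by 0.38, scaling without the named gene families by −0.13 and the aged WT mix by 0.34. The filter of at least 500 UMIs and under 5% mitochondrial UMIs removed no annotated cell and gives no values. No paired analysis was possible because each group is 1 pool of mice.

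With age, the T follicular helper median was 0.98 with the aged WT mix of types, 1.83 as a mean over cells, 1.81 as a mean over members, −0.11 within Nai Cd8 and 0.54 within Mem Cd8, where the regulatory T median was −0.29. The naive T median was −0.49 with TMM scaling, −0.46 with scaling without immunoglobulin and the other gene families, −0.27 with the aged WT mix, −0.49 as a mean over cells or members, −0.088 within Nai Cd4, −1.37 within Mem Cd4 and −0.014 within Nai Cd8. The cytotoxic T median was 0.64 with the aged WT mix and within Mem Cd8, 0.040 within Nai Cd4, 0.68 within Mem Cd4 and 0.29 within Nai Cd8. With the aged WT mix, the myeloid interferon gamma median was 0.000458 and the log2 ratio of Chil3 −0.043, a mix that leaves Gran out.

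In the miR-146a knockout against aged WT, the regulatory T median was 0.91 with scaling without immunoglobulin and the other gene families, 0.61 with the aged WT mix, 0.88 as a mean over cells, 0.68 within Mem Cd4 and 0.77 within Mem Cd8. The naive T median was −1.34, −0.82 and −1.31 in the first 3 of these, −1.09 as a mean over members, −0.92 within Nai Cd4, −0.51 within Mem Cd4, −0.49 within Nai Cd8 and −0.67 within Mem Cd8. The cytotoxic T median was 1.74 within Nai Cd4 and 0.42 within Mem Cd4. Within Mem Cd4 the T follicular helper median was −0.10 and the cell cycle median −0.027. The miR-146a target median was −0.18 within Nai Cd8. The germinal centre B median was 0.68 with the aged WT mix.

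In the double knockout against the miR-146a knockout, the naive T median was 0.52 with the aged WT mix, 0.59 within Nai Cd4, 0.24 within Mem Cd4, 0.30 within Nai Cd8 and 0.56 within Early Act Cd8. The cytotoxic T median was −0.38, −0.11, −0.71 and −0.47 within the same types. The effector memory median was 0.20 within Mem Cd4, 0.030 within Mem Cd8 and 0.00297 within Early Act Cd8, and the exhaustion median 0.17 within Mem Cd4. The interferon gamma median was 0.50 within Early Act Cd8, the cell cycle median 0.00487 within Nai Cd4 and −0.032 in myeloid cells without Gran, and the immediate early median 0.065 within Nai Cd8 and 0.15 within Early Act Cd8. Without Scrublet doublets the myeloid type I interferon median was −0.0095 and the T/B dbl share ratio 0.95. The erythroid median in B cells was 0.40 with the aged WT mix, 0.42 as a mean over cells and 0.064 as a mean over members, but −2.08 without cells led by erythroid, platelet or progenitor markers. The cause was not tested; the aged WT mix fixes type proportions and also leaves out types with under 30 cells in either library. Depth limits types with few cells, such as the 14 Early Act Cd8 cells of aged WT.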

Other observations

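No test of an explanation is reported in this part. The values by type were chosen only after the results were seen. Several T cell genes were read by type across the 4 libraries. In Mem Cd4 cells Spp1 was at 0, 195, 255 and 454 CPM in young WT, aged WT, the miR-146a knockout and the double knockout, Sostdc1 at 50.7, 616, 879.6 and 1048 CPM, and Il1r2 at 2.60, 95.3, 211 and 178 CPM. In Early Act Cd8 cells, 70, 14, 35 and 43 in number, Il1r2 was at 0, 124, 552 and 267 CPM. Unlike Gzmb in Mem Cd8 cells (26.5, 38.0, 458 and 69.4 CPM), Lag3 in Mem Cd4 cells was at 52.0, 467, 554 and 529 CPM. Gzmk in Mem Cd8 cells was at 26.5, 194, 525 and 221 CPM. Foxp3 was read in cells annotated as Nai Cd4 as well as Mem Cd4, with 7, 41, 57 and 48 UMIs in the former. In Ly6c+ monocytes Chil3 was at 1105, 1072, 1080.3 and 1149.5 CPM.

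Some annotated types held markers of more than 1 kind of cell. Over the 4 libraries together, genes leading the cells annotated as Trans B included the precursor genes Igll1, Vpreb1, Rag1 and Dntt, but of the 568 Vpreb1 UMIs in these cells 343 came from the miR-146a knockout and 222 from the double knockout. DC/Mac cells were led by macrophage genes (C1qa), plasmacytoid dendritic cell genes (Siglech) and mast cell or basophil genes (Cpa3, Prss34). In the aged WT library their C1qa UMIs numbered 0, against 109 in young WT, 855 in the miR-146a knockout and 246 in the double knockout. Within cells annotated as GC Centrocyte, 3, 2, 6 and 7 cells had more erythroid, platelet and progenitor than B marker UMIs.

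Haemoglobin and antibody transcripts were found in classes that should lack them. Hbb-bs was found in 1.45%, 0.376%, 15.8% and 2.31% of B cells. Jchain in T cells was at 18.7, 62.0, 66.4 and 70.3 CPM.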
